A study of Mus musculus with 15 samples.

How the data were processed

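RNA of 15 samples was hybridised to Affymetrix mouse expression arrays after labelling in 2 cycles, per the labels' protocols. The design had 5 groups of 3 biological replicates: ES cells at day 0, and cells grown in RDL or CDL medium and sorted at day 4 or day 6. Per the submitters' processing notes, the intensity values were made with MAS5, and they were taken as deposited, 1 signal intensity per probe set on a linear scale. The values do not settle the summarisation further: the trimmed mean (2% from each end) lay between 149 and 157 across arrays, and 3 arrays shared the maximum value of 17931. No detection calls were used here, and the genome build behind the annotation is not given in the sources used here. The MAS5 version is not given either.

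Of 45101 probe sets, 64 controls were left out. Among the other 45037, 34945 carried 1 gene symbol, 932 carried several and 9160 had no symbol in the annotation used here. A constant c of 12.6, the median over arrays of each array's 25th percentile, was added before taking log2. Probe sets above their array's 50th percentile in at least 3 of the 15 arrays were kept, and each gene was represented by its single-symbol probe set with the highest mean. Of 18193 genes with such a probe set, 12400 were tested and 5793 were left out as dim. No values were missing and 0 pairs of arrays were identical. Array medians lay between 29.4 and 31.2 and maxima between 16039 and 17931. The ratio of 3' to 5' signal lay between 0.974 and 1.11 for Gapdh and between 1.43 and 1.90 for actin.

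Group means were fitted over all arrays with limma 3.58.1 in R 4.3.3, with moderated t-tests (eBayes with an intensity trend) and Benjamini-Hochberg adjustment over the genes tested, and genes with an adjusted p under 0.05 were counted. There were 7 comparisons: each medium at day 4 against ES cells, CDL against RDL at day 4 and at day 6, day 6 against day 4 in each medium, and the interaction of medium and day. Day 6 differed from day 4 also in cell line, strain and sort reporter. At an unadjusted p under 0.05 the comparison of media called 1843 genes at day 4 and 2386 at day 6. The median difference over genes was between -0.02 and 0.00 in all 7. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

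Named genes followed a rule. For each comparison these were the 10 with the largest increase and the 10 with the largest decrease past the threshold whose 3 arrays in one group did not overlap the 3 in the other, so that all 3 arrays showed the direction, a separation that chance gives in 10% of genes. For the interaction these were the 5 largest each way. The reporter genes Msgn1 and Pax3 were named throughout, and from a described list up to 4 members with the largest differences past the threshold. Symbols of clones and predicted genes were passed over. Of 79 other probe sets of the called genes named by size or as reporters, 72 gave the same call, 7 gave none and 0 gave an opposite one. The 7 were all in the comparison of media at day 4, where the other probe sets numbered 16, and for Mt1 and Sim1 no other was called. Members named for their list alone were not counted here, and not all their other probe sets were called. For Nkd1 in RDL day 4 against ES cells 2 of 3 gave the same call. These choices, the comparisons and the alternatives were set before the data were examined, except where a choice is said to have come later.

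Genes were also tested in 34 lists written from general knowledge: pluripotency, primed epiblast, primitive streak and tail bud, posterior presomitic mesoderm, Notch and segmentation clock, Wnt, FGF and ERK, and BMP targets, retinoic acid pathway, anterior presomitic mesoderm and somite, dermomyotome, sclerotome, neural crest, neural, lateral plate, intermediate mesoderm, endothelium and blood, endoderm, notochord, epithelial, mesenchymal, embryonic fibroblast, Hox groups 1 to 5, 6 to 9 and 10 to 13, glycolysis, cholesterol synthesis, mitosis, p53 targets, immediate early and heat shock, imprinted, sex chromosome, germline and the sort reporters. Camera was run with a preset correlation of 0.01 between genes on the 32 lists with at least 3 tested members, with adjustment over 224 tests. It was repeated with the correlation estimated from the data, and with fry. Of the lists left out, Hox groups 10 to 13 had 1 tested member and the reporters had 2. Pax3, on whose reporter the day 6 cells were sorted, is also a member of the anterior presomitic and somite list and of the dermomyotome list. Lists share other members too, so their tests are not independent. Aldh1a2 is in the somite and retinoic acid lists, and Foxc2 in the somite and sclerotome lists. Fgf8 is in the streak and posterior presomitic lists, and Dll1 in the posterior presomitic and Notch lists.

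Replicates were checked for pairing through the correlation of their residuals. Replicates with the same number in RDL day 6 and RDL day 4 correlated at 0.22 to 0.28, each of the 3 best with its own number, which met the rule for pairs. With replicate number as a block this comparison called 4210 genes, against 3838 without it. Of its 10 splits, 4 part all pairs, the real one among them, and the highest count of the other 3 was 0. Those 3 mix day 4 and day 6 arrays, which widens the spread within their groups, so that 0 tells little.

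The share of ES signal on an array was computed per gene as the array minus the mean of its group mates, over the ES mean minus the mates' mean, for genes with an ES signal over 500 and at least 8 times that of the mates. A mirror set held genes with the reverse ratio, and CDL day 4 replicate 1 was never among the mates. This measure was chosen after the arrays had been compared. Alternatives were other constants (1 and 30.3), no filter or a filter at the 75th percentile, quantile normalization, median centring, all probe sets, the mean of a gene's probe sets, no intensity trend, array weights, only the groups compared, the replicate block, each replicate left out, and a 2-fold minimum. Leaving out CDL day 4 replicate 1 and RDL day 6 replicate 1 together was added after seeing the data.

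The steps were tested on simulated data for the comparison of media at day 4. Each gene's spread was that of the fit over all 15 arrays and equal on every array, so uneven arrays were not reproduced. Of 50 genes changed at each size, 54% were found at a log2 change of 0.5, 98% at 1, and 100% at 2 and at 3, with 11 false calls among unchanged genes. A list of 15 genes shifted by 0.5 was found, and 0 of 30 unchanged lists were called. The genes were drawn independently of each other, so this cannot show false calls that come from correlation between genes.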

Results

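Gene expression was measured on 15 Affymetrix arrays of mouse embryonic stem (ES) cells and of cells made from them, in 5 groups of 3 biological replicates. ES cells of line E14 were taken at day 0, unsorted, from medium with LIF, a GSK3 inhibitor and a MEK inhibitor. The other 4 groups were differentiated without serum, with BMP4 at 10 ng/ml for 2 days and then with 0.5% DMSO and the BMP receptor inhibitor LDN at 0.1 µM. To these was added either the Wnt agonist Rspo3 at 10 ng/ml (RDL medium) or the GSK3 inhibitor CHIR at 1 µM (CDL medium). At day 4, E14 cells were sorted for a fluorescent reporter of Msgn1, and at day 6, cells of another line, CK35, were sorted for GFP made under Pax3. Array medians lay between 29.4 and 31.2 signal units and upper quartiles between 119 and 135, and the number of arrays limits the precision.

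Across genes, the mean correlation of an array with its group mates lay between 0.978 and 0.997. CDL day 4 replicate 1 stood nearer to the ES arrays (mean r 0.899) than the other arrays of its group (0.839 and 0.840). Over 102 genes that were bright in ES cells and dim in its group mates, this array held a median of 19.7% of the ES signal (interquartile range 16.7% to 22.3%). The other 11 sorted arrays lay between -0.373% and 0.581% on the same measure. RDL day 6 replicate 1 had the lowest mean correlation with its mates (0.978) and the highest ratio of 3' to 5' actin signal (1.90, against 1.43 on the lowest array). The ES arrays came near it at 1.77, 1.80 and 1.85, and the Gapdh ratio of RDL day 6 replicate 1 was 1.02. Counts without CDL day 4 replicate 1 and RDL day 6 replicate 1, an alternative chosen after seeing the data, stand beside the comparisons. All comparisons share 1 estimate of the spread, so these arrays also act on comparisons they do not enter.

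**Figure D1:**
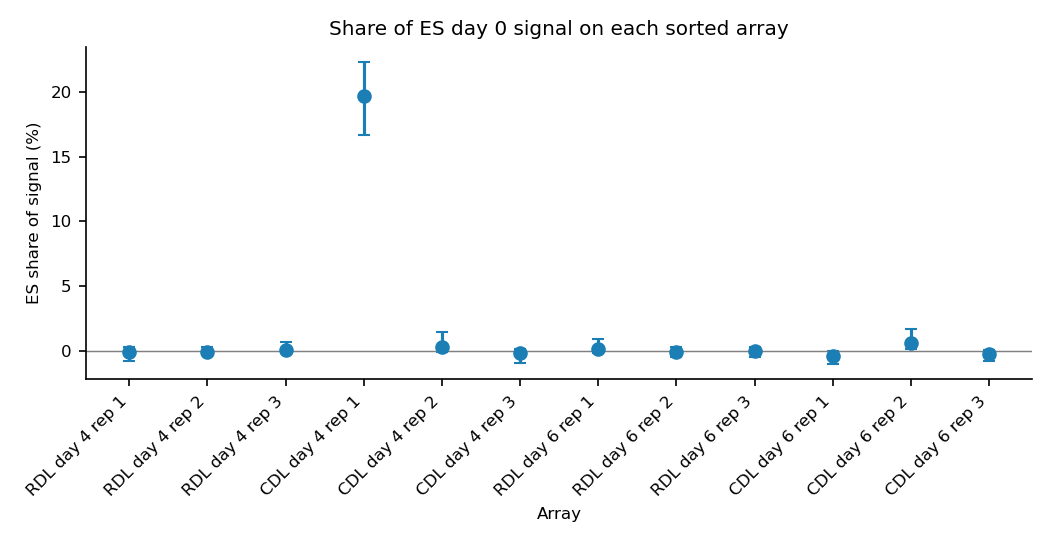
Share of the ES day 0 signal (percent, vertical axis) on each of the 12 sorted arrays (horizontal axis), with the median over genes bright in ES cells and dim in the array's group as a point and the interquartile range as a bar. CDL day 4 replicate 1 lies at 19.7% and the other 11 arrays lie between -0.373% and 0.581%.

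The reporter genes followed the sorts. Msgn1, a transcription factor of the presomitic mesoderm, had a mean signal of 29.1 ± 5.99 (SD, n = 3) in ES cells, 196 ± 46.6 in RDL and 337 ± 27.4 in CDL at day 4, and 28.7 ± 2.61 in RDL and 43.9 ± 0.370 in CDL at day 6. Pax3, a paired-box gene of the anterior presomitic mesoderm and the dermomyotome, had a mean signal of 58.9 ± 5.24 in ES cells, 108 ± 9.16 and 54.7 ± 6.99 in RDL and CDL at day 4, and 303 ± 57.7 and 522 ± 91.9 at day 6. All differences below are on the log2(signal + 12.6) scale, which understates the change of dim genes and makes their size and rank depend on the constant, and carry the standard error (SE) of limma's fit with n = 3 arrays per group. List means carry the SE over their members.

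**Figure D2:**
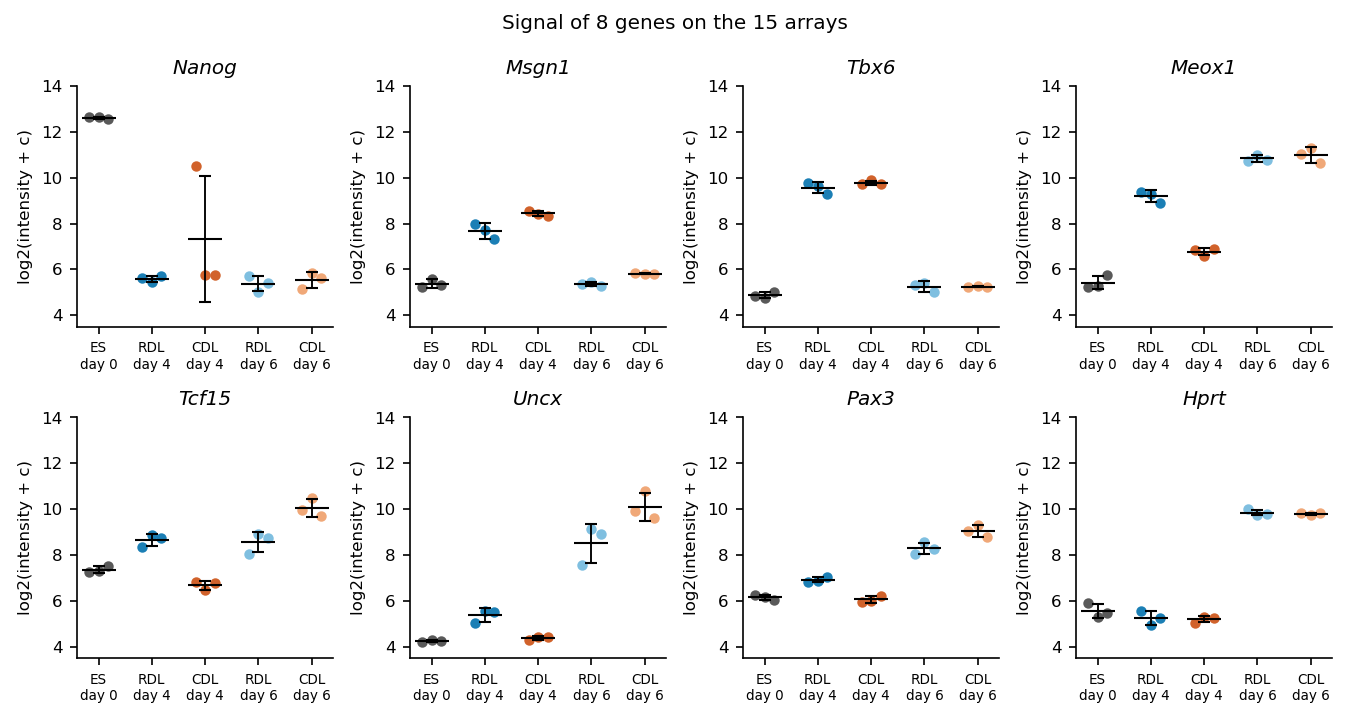
Signal of 8 genes on the 15 arrays as log2(intensity + c) with c = 12.6, by group (horizontal axis), where points are arrays and the bars give the mean and SD of 3 arrays. Msgn1 and Tbx6 were high at day 4, Pax3 and Uncx at day 6, and on CDL day 4 replicate 1 Nanog stood far above the other arrays of its group.

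What the Msgn1 reporter-positive cells of RDL medium expressed relative to ES cells was the first comparison. The largest increases included those of Aplnr, the apelin receptor (7.74 ± 0.18, adjusted p = 5.19e-14), Igf2, an imprinted growth factor (6.48 ± 0.13), the immediate early gene Egr1 (6.41 ± 0.17), the anterior Hox gene Hoxb1 (6.26 ± 0.18), the Notch ligand Dll1 (6.08 ± 0.25) and Rspo3 itself (6.02 ± 0.14). Car3, a carbonic anhydrase (6.13 ± 0.17), and Tagln, which binds actin (5.96 ± 0.19), were also among the 10 that rose most. As the mean of their probe sets Car3 stood at 3.82 and Rspo3 at 3.81. Aplnr had a mean signal of 5.67 ± 0.490 in ES cells, below the constant, and its increase lay between 4.96 and 9.19 over its alternatives, that of Igf2 between 3.68 and 6.83 and that of Egr1 between 5.74 and 7.12. The largest decreases included the pluripotency factors Nanog (-7.00 ± 0.83, adjusted p = 2.30e-06) and Tfcp2l1 (-6.83 ± 0.79), the ribosomal protein paralogue Rpl39l (-7.04 ± 0.93), the germline gene Morc1 (-6.83 ± 0.79) and Bhmt, an enzyme of methionine metabolism (-6.13 ± 0.62). Msgn1 rose by 2.30 ± 0.14 and Pax3 by 0.76 ± 0.15. Of 12400 genes tested, 3422 were higher and 3657 lower at adjusted p under 0.05, and 1204 and 1231 of these differed at least 2-fold. Without the 2 arrays that stood apart, which act here only through the shared spread, 3760 were higher and 3950 lower.

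All 13 posterior presomitic mesoderm genes rose (mean 3.54 ± 0.49, adjusted p = 6.78e-10, and adjusted p = 0.0154 with an estimated correlation). These included Pcdh8, a protocadherin of the forming somite, at 4.96 and Fgf8 at 4.76. Of the 13 primitive streak and tail bud genes, 11 rose and none fell (adjusted p = 3.78e-06, and adjusted p = 0.0156 with an estimated correlation), among them Wnt5a at 4.38 and Mixl1 at 4.11. In the Notch and segmentation clock list 13 of 14 rose (adjusted p = 1.70e-05, and adjusted p = 0.185 with an estimated correlation). Examples were Nrarp at 4.52, Dll3 at 4.20 and the oscillating repressor Hes7 at 3.78. Genes of the anterior presomitic mesoderm and somite were 12 up and 2 down of 15 (adjusted p = 0.000198, and adjusted p = 0.208 with an estimated correlation). Among them were the forkhead genes Foxc1 at 5.82 and Foxc2 at 5.06 and Meox1 at 3.78. All 13 Hox genes of paralogue groups 1 to 5 rose (mean 2.92 ± 0.40, adjusted p = 1.09e-08, and adjusted p = 0.157 with an estimated correlation), as did 7 of 9 of groups 6 to 9 (adjusted p = 0.000498, and adjusted p = 0.157 with an estimated correlation). The mesenchymal list rose in 9 of 10 members (adjusted p = 6.53e-05, and adjusted p = 0.0885 with an estimated correlation). These included N-cadherin (Cdh2) at 5.40 and Twist1 at 3.19. Lists of sclerotome (2 higher and 0 lower of 6, adjusted p = 0.0823), intermediate mesoderm (2 and 0 of 3, adjusted p = 0.0578) and lateral plate (4 and 1 of 10, adjusted p = 0.101) were not past the threshold.

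Pluripotency genes fell. Of 23, 20 fell and 2 rose (mean -3.66 ± 0.52, adjusted p = 7.24e-07, and adjusted p = 0.353 with an estimated correlation). Examples were Zfp42 at -6.01 and Esrrb at -5.69. The members that rose were Gbx2 (2.61), a homeobox gene that also patterns the posterior embryo, and Lin28a (1.88), an RNA-binding protein that blocks let-7. All 5 germline genes fell (adjusted p = 0.000433, and adjusted p = 0.157 with an estimated correlation), led by Dazl at -4.37 and Sycp3 at -2.97. In glycolysis 11 of 15 fell and 2 rose (adjusted p = 0.00873, and adjusted p = 0.433 with an estimated correlation). Among them were the kinases Pfkp at -4.28 and Hk1 at -2.11. Each of these counts was the same when adjusted over the list alone.

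Of 12 FGF and ERK targets 9 rose and 1 fell (adjusted p = 0.000233, and adjusted p = 0.320 with an estimated correlation). These included the ERK phosphatases Dusp6 at 4.41 and Dusp4 at 4.13. BMP targets, with 4 higher and 2 lower of 9, were not past the threshold as a list (adjusted p = 0.203). Of 11 genes in the immediate early and heat shock list, 7 rose and 2 fell (adjusted p = 0.0164, and adjusted p = 0.320 with an estimated correlation). Fos rose (5.65), and the genes that fell were Hspb1 (-3.87) and Hspa1b (-1.47). Among Wnt targets 9 of 14 rose and 2 fell (adjusted p = 0.00300, and adjusted p = 0.369 with an estimated correlation). Among them were Lef1 at 4.91 and Nkd1 at 3.85. In the retinoic acid pathway 6 of 10 rose and 1 fell (adjusted p = 0.00280, and adjusted p = 0.134 with an estimated correlation). These included the synthesising enzyme Aldh1a2 at 5.28 and the degrading enzyme Cyp26a1 at 3.09. Imprinted genes rose in 15 of 18 cases with 1 fall (adjusted p = 1.47e-07, and adjusted p = 0.117 with an estimated correlation). Examples were Phlda2 at 4.64, Ndn at 4.36 and Peg3 at 3.75. Dermomyotome genes rose in 6 of 9 cases (adjusted p = 0.0243, and adjusted p = 0.208 with an estimated correlation). A list of embryonic fibroblast genes, kept as a marker set for feeder cells, rose in 7 of 10 (adjusted p = 0.000785, and adjusted p = 0.0405 with an estimated correlation). Among them were the contractile genes Tagln at 5.96 and Acta2 at 5.25 above the collagens Col3a1 at 2.67 and Col1a2 at 2.45. Counts adjusted over the list alone equalled those over all genes in each of these lists. The ES cells were unsorted and the day 4 cells sorted. The ES cells also came from medium with LIF, a GSK3 inhibitor and a MEK inhibitor, and the day 4 cells from another medium. Medium, sort and differentiation thus entered this comparison together, as they did that of CDL with ES cells, and cannot be told apart.

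The same question was asked of CDL medium, where CHIR replaced Rspo3. Aplnr (7.95 ± 0.18, adjusted p = 3.45e-14), Hoxb1 (6.73 ± 0.18), Car3 (6.71 ± 0.17), Rspo3 (6.37 ± 0.14), Egr1 (6.31 ± 0.17), Dll1 (5.99 ± 0.25), the cardiac actin gene Actc1 (5.84 ± 0.17) and Fos (5.72 ± 0.15) were among the 10 largest increases. Over alternatives Aplnr lay between 5.19 and 9.40, Car3 between 4.48 and 7.19, Rspo3 between 4.22 and 7.18 and Egr1 between 5.65 and 7.03, so their order was not fixed. Nanog fell by 5.27 on the log2 scale (SE 0.83, adjusted p = 5.12e-05). It fell by 6.85 without CDL day 4 replicate 1. Over the alternatives of Nanog the adjusted p lay between 2.23e-15 and 0.00344. Crxos (-5.31 ± 0.77), Morc1 (-5.30 ± 0.79) and Tfcp2l1 (-5.24 ± 0.79) also fell. Without CDL day 4 replicate 1 these stood at -6.81, -6.83 and -6.78. Without replicate 2 or 3 of that group, Nanog and these genes lay between -4.57 and -4.45. Msgn1 rose by 3.07 ± 0.14, whereas Pax3 differed by -0.09 ± 0.15 (adjusted p = 0.631). In all, 3302 genes were higher and 3665 lower, and 3573 and 3926 without the 2 arrays that stood apart. Of those 2 only CDL day 4 replicate 1 is in this comparison, and without it alone 3194 were higher and 3620 lower.

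All 13 posterior presomitic mesoderm genes rose in CDL too (mean 3.57 ± 0.46, adjusted p = 7.29e-11, and adjusted p = 0.0152 with an estimated correlation). These included the T-box gene Tbx6 at 4.91. Primitive streak genes rose in 12 of 13 (adjusted p = 3.05e-08, and adjusted p = 0.0130 with an estimated correlation). Examples were Fgf8 at 4.97 and Wnt5a at 4.43. All 13 Hox genes of groups 1 to 5 rose (adjusted p = 9.68e-09, and adjusted p = 0.157 with an estimated correlation). Wnt targets rose in 11 of 14 and fell in 2 (adjusted p = 0.000427, and adjusted p = 0.298 with an estimated correlation). Among them were Lef1 at 4.96, Nkd1 at 3.95 and Sp8 at 3.06. Of 15 anterior presomitic and somite genes, 5 rose, 2 fell and 8 did not pass, and the list test was not past the threshold (mean 0.97 ± 0.51, adjusted p = 0.131). Pluripotency genes fell in 20 of 23 and rose in 2 (mean -2.69 ± 0.46, adjusted p = 2.50e-05, and adjusted p = 0.410 with an estimated correlation), on arrays of which 1 held 19.7% of the ES signal, and without that array the list mean was -3.38 with the same counts. Counts adjusted over the list alone were equal to these.

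The remaining lists past the threshold in CDL against ES cells were those that had moved in RDL, with the same counts adjusted over the list alone unless given. Notch and segmentation clock genes (11 higher and 0 lower of 14, adjusted p = 4.80e-05, and adjusted p = 0.208 with an estimated correlation) included Nrarp at 4.08. Hox genes of groups 6 to 9 (5 higher and 0 lower of 9, adjusted p = 0.00340, and adjusted p = 0.208 with an estimated correlation) and mesenchymal genes (8 higher and 0 lower of 10, adjusted p = 5.71e-05, and adjusted p = 0.0885 with an estimated correlation) had higher means. FGF and ERK targets (9 higher and 1 lower of 12, adjusted p = 0.000131, and adjusted p = 0.302 with an estimated correlation) included Dusp6 at 4.21. Imprinted genes (15 higher and 2 lower of 18, adjusted p = 7.18e-08, and adjusted p = 0.108 with an estimated correlation) and retinoic acid genes (5 higher and 2 lower of 10, 6 and 2 adjusted over the list alone, adjusted p = 0.0135, and adjusted p = 0.173 with an estimated correlation) had higher means, and so had immediate early and heat shock genes (7 higher and 2 lower of 11, adjusted p = 0.0117, and adjusted p = 0.298 with an estimated correlation). The embryonic fibroblast list also passed (6 higher and 0 lower of 10, adjusted p = 0.00147, and adjusted p = 0.0519 with an estimated correlation). Glycolysis (2 higher and 11 lower of 15, adjusted p = 0.0310, and adjusted p = 0.526 with an estimated correlation) and germline genes (0 higher and 4 lower of 5, adjusted p = 0.00512, and adjusted p = 0.241 with an estimated correlation) had lower means.

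The 2 comparisons with ES cells shared 2953 higher and 3250 lower genes, and 7 genes moved in opposite directions. Independent lists of these sizes would share 911 and 1081. When all arrays were simulated without change, with the simulated ES arrays entering both comparisons, a mean of 0.02 calls was shared over 100 draws. With no change simulated few calls arise, so this overlap had to be near 0. It cannot gauge what shared ES arrays add where many genes differ. Across genes, which are not independent replicates, the log2 differences correlated at r = 0.97, against 0.50 in the simulation, with a covariance of 0.978 against 0.00987. The ES arrays entered both comparisons, and part of the excess may come from them, since 3 arrays are too few to be split.

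The direct comparison of the media at day 4 kept line, day and sort the same. Genes of the forming somite were lower in CDL than in RDL: the homeobox gene Meox1 (-2.42 ± 0.18, adjusted p = 1.24e-06), the paraxis gene Tcf15 (-1.96 ± 0.22), Ripply2, which ends the presomitic program (-1.69 ± 0.11), and Dmrt2 (-1.67 ± 0.26). The nuclear receptor Nr2f2 (-1.65 ± 0.19, and -0.70 as the mean of its probe sets), the Hox cofactor Meis1 (-1.60 ± 0.16) and the ephrin Efnb2 (-1.54 ± 0.26) were lower too. Higher in CDL were the metallothioneins Mt1 (2.07 ± 0.20, and 1.07 as the mean of its probe sets) and Mt2 (1.80 ± 0.19), the pluripotency genes Dppa2 (1.88 ± 0.42) and Pou5f1 (1.62 ± 0.30), which stood at 1.12 and 1.13 without CDL day 4 replicate 1, and the neuropeptide gene Spx (1.71 ± 0.09). Msgn1 was higher in CDL (0.77 ± 0.14) and Pax3 lower (-0.85 ± 0.15). Fewer genes differed than against ES cells, with 359 higher and 188 lower, and 52 and 44 of them at least 2-fold.

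Of 15 anterior presomitic and somite genes, 9 were lower and 1 was higher in CDL (11 and 1 adjusted over the list alone, mean -0.99 ± 0.20, adjusted p = 2.66e-14, and adjusted p = 0.0265 with an estimated correlation), and 7 were lower and 0 higher without CDL day 4 replicate 1. Dermomyotome genes were lower in 5 of 9 cases, the same adjusted over the list alone, where 1 was higher (adjusted p = 1.67e-07, and adjusted p = 0.0156 with an estimated correlation). These included Sim1 at -1.52 (-0.77 as the mean of its probe sets), the receptor gene Met at -1.19 and Eya1 at -1.17. Primitive streak and tail bud genes went the other way, with 6 of 13 higher (9 higher and 1 lower adjusted over the list alone, mean 0.37 ± 0.12, adjusted p = 1.30e-08, and adjusted p = 0.0130 with an estimated correlation), among them Evx1 at 0.83, Cdx4 at 0.79 and Mixl1 at 0.69. Hox genes of groups 6 to 9 were lower in 4 of 9 (5 adjusted over the list alone, adjusted p = 6.53e-05, and adjusted p = 0.134 with an estimated correlation), and in 1 without that array. Retinoic acid genes were lower in 3 of 10 (4 adjusted over the list alone, adjusted p = 0.00312, and adjusted p = 0.134 with an estimated correlation). An example was the receptor Rarb at -1.22. The lists of sclerotome (2 of 6 lower, 3 adjusted over the list alone, adjusted p = 0.00631, and adjusted p = 0.288 with an estimated correlation) and intermediate mesoderm (2 of 3 lower, the same over the list alone, adjusted p = 0.00145, and adjusted p = 0.157 with an estimated correlation) also had lower means. Without that array 0 sclerotome genes and 1 of intermediate mesoderm were past the threshold.

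Pluripotency genes were higher in CDL as a list (4 of 23, the same adjusted over the list alone, mean 0.97 ± 0.10, adjusted p = 1.30e-08, and adjusted p = 0.288 with an estimated correlation), namely Dppa2, Pou5f1, Klf5 (1.27) and Fgf4 (1.03). CDL day 4 replicate 1, with 19.7% of the ES signal, is in this comparison. Without it the mean of the list was 0.27 ± 0.09 (adjusted p = 0.000944), and 4 members were past the threshold. Germline genes were higher in 2 of 5, the same over the list alone, with a mean of 0.59, and 0.36 without CDL day 4 replicate 1 (adjusted p = 4.99e-05, and adjusted p = 0.134 with an estimated correlation). Among them were Sycp3 at 0.98 and Ddx4 at 0.83. Epithelial genes were higher in 4 of 12 (7 adjusted over the list alone, adjusted p = 1.70e-05, and adjusted p = 0.211 with an estimated correlation). These included E-cadherin (Cdh1) at 1.43 and the claudin Cldn4 at 1.23. The glycolysis list passed with no member past the threshold, over all genes or adjusted over the list alone (adjusted p = 0.0382, and adjusted p = 0.534 with an estimated correlation), and gave an adjusted p of 0.691 without that array. Wnt targets had a higher mean in CDL (1 higher and 0 lower of 14, 4 and 0 adjusted over the list alone, adjusted p = 0.0350, and adjusted p = 0.518 with an estimated correlation). Lateral plate genes had a lower one (0 higher and 2 lower of 10, 0 and 3 adjusted over the list alone, adjusted p = 0.0232, and adjusted p = 0.135 with an estimated correlation), with 1 lower without that array.

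The count of 547 fell to 341 without RDL day 4 replicate 2 and to 353 without RDL day 4 replicate 1, and was 634 without the 2 arrays that stood apart. Of those 2 only CDL day 4 replicate 1 is in this comparison, and without it alone the count fell to 392. Dppa2 was not past the threshold when the 6 arrays were fitted alone (adjusted p = 0.108, with 0.000325 to 0.108 over its alternatives). It was not past it either without RDL day 4 replicate 1 (0.0515), 2 (0.0646) or 3 (0.0506). Chchd10, a mitochondrial protein, was higher in CDL by 2.18 ± 0.42, and by 1.39 without CDL day 4 replicate 1. Its adjusted p was 0.0780 in the fit of 6 arrays and lay between 2.67e-05 and 0.0780 over its alternatives.

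From the Msgn1-sorted cells of day 4 to the Pax3-sorted cells of day 6 in RDL medium, line, strain and reporter changed with the day. Igfbp5, which binds insulin-like growth factors (6.68 ± 0.22, adjusted p = 2.58e-12, and 3.73 as the mean of its probe sets), the matrix genes Tgfbi (5.47 ± 0.19) and Col3a1 (4.63 ± 0.12), the nuclear receptor Nr2f1 (4.79 ± 0.18) and the somite gene Meox2 (4.78 ± 0.17) rose most. The imprinted gene Phlda2 (-5.56 ± 0.15) fell most, followed by Dll1 (-4.77 ± 0.25), the muscle actin gene Acta1 (-4.58 ± 0.16), the galectin Lgals3 (-4.50 ± 0.11), Nrarp (-4.45 ± 0.25), Mid1 (-4.35 ± 0.20, and -3.04 as the mean of its probe sets) and Hoxb1 (-4.34 ± 0.18). Tbx6 (-4.31 ± 0.13) and Dll3 (-4.23 ± 0.17), of the presomitic mesoderm, were also among the 10 largest decreases. Hprt, a purine salvage enzyme, rose by 4.60 ± 0.16. Msgn1 fell by 2.31 on the log2 scale and Pax3 rose by 1.37 ± 0.15. In total 1711 genes were higher and 2127 lower, and 1795 and 2044 without the 2 arrays that stood apart, of which RDL day 6 replicate 1 enters here. Without that array alone 1671 were higher and 1885 lower. With each array centred on its median 1947 were higher and 1828 lower.

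Primitive streak and tail bud genes fell in 12 of 13 (mean -1.85 ± 0.40, adjusted p = 7.84e-12, and adjusted p = 0.00468 with an estimated correlation). Examples were Mixl1 at -4.22, Fgf8 at -4.21 and Cdx1 at -3.60. Posterior presomitic mesoderm genes fell in 10 and rose in 2 of 13 (adjusted p = 2.62e-09, and adjusted p = 0.0156 with an estimated correlation), the rises being Dkk1 (0.90), a Wnt antagonist, and Cyp26a1 (0.86). Wnt targets fell in 10 of 14 and rose in 1 (11 and 1 adjusted over the list alone, adjusted p = 1.52e-07, and adjusted p = 0.157 with an estimated correlation). Among them were Cdx1 at -3.60, Tnfrsf19 at -3.53 and Sp5 at -3.38. Notch genes fell in 9 and rose in 1 of 14 (adjusted p = 1.87e-05, and adjusted p = 0.185 with an estimated correlation). These included Nrarp at -4.45 and Hes7 at -3.89. FGF and ERK targets fell in 10 and rose in 2 of 12 (adjusted p = 0.00160, and adjusted p = 0.381 with an estimated correlation). Examples were Etv5 at -2.42 and Spred2 at -1.68. Targets of p53 fell in 10 of 11 (mean -1.06 ± 0.19, adjusted p = 7.19e-07, and adjusted p = 0.0152 with an estimated correlation). Among them were Phlda3 at -1.88 and Perp at -1.85. Epithelial genes fell in 7 of 12 (7 and 1 rise adjusted over the list alone, adjusted p = 0.00121, and adjusted p = 0.364 with an estimated correlation). These included the keratin Krt19 at -3.46.

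Sclerotome genes rose in 5 of 6 (mean 1.71 ± 0.48, adjusted p = 2.94e-05, and adjusted p = 0.134 with an estimated correlation). Examples were Pax1 at 2.82, the cartilage collagen Col2a1 at 2.74 and Sox9 at 2.42. Dermomyotome genes rose in 5 and fell in 1 of 9 (6 and 1 adjusted over the list alone, adjusted p = 0.00543, and adjusted p = 0.157 with an estimated correlation). Among them were Sim1 at 2.27 and Met at -0.96. Imprinted genes rose in 12 and fell in 2 of 18 (adjusted p = 9.61e-06, and adjusted p = 0.157 with an estimated correlation). These included Dlk1 at 3.43, Mest at 3.11 and Nnat at 2.67. Endoderm genes rose in 5 of 7 (adjusted p = 0.000510, and adjusted p = 0.157 with an estimated correlation). Examples were Sox17 at 2.34 and Foxa1 at 1.97. Cholesterol synthesis (5 higher and 0 lower of 16, adjusted p = 0.00520, and adjusted p = 0.181 with an estimated correlation) and mesenchymal genes (4 higher and 1 lower of 10, adjusted p = 0.0355, and adjusted p = 0.293 with an estimated correlation) had higher means. Intermediate mesoderm (0 higher and 3 lower of 3, adjusted p = 0.00594, and adjusted p = 0.208 with an estimated correlation), Hox genes of groups 1 to 5 (0 higher and 6 lower of 13, adjusted p = 0.00326, and adjusted p = 0.433 with an estimated correlation) and pluripotency genes (0 higher and 9 lower of 23, adjusted p = 0.00416, and adjusted p = 0.572 with an estimated correlation) had lower means. Anterior presomitic and somite genes were not past the threshold as a list (7 higher and 4 lower of 15, 7 and 5 adjusted over the list alone, mean 0.51 ± 0.52, adjusted p = 0.166), and were past it without the 2 arrays that stood apart (adjusted p = 0.0458). Without these arrays 8 cholesterol genes were higher. Where no other number is given, the counts of this comparison were the same adjusted over the list alone. Because line, strain and reporter changed with the day, none of these differences can be assigned to 1 of them.

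In CDL medium the same step came with the same changes of line, strain and reporter. Igfbp5 (7.27 ± 0.22, adjusted p = 9.22e-13, and 3.94 as the mean of its probe sets), Uncx, a homeobox gene of the posterior part of each somite (5.72 ± 0.33), the selenium carrier Selenop (5.28 ± 0.14), Foxd1 (4.97 ± 0.23) and the chemokine Cxcl12 (4.63 ± 0.23) rose most. Phlda2 (-5.25 ± 0.15), Lgals3 (-5.22 ± 0.11), Mixl1 (-5.07 ± 0.10), the guanylate-binding protein Gbp2 (-4.67 ± 0.16), Fgf8 (-4.57 ± 0.12) and Tbx6 (-4.53 ± 0.13) fell most. Pax3 rose by 2.98 ± 0.15 and Msgn1 fell by 2.63 on the log2 scale. Hprt rose by 4.60 ± 0.16, as in RDL. There were 2155 genes higher and 2726 lower, and 2431 and 2897 without the 2 arrays that stood apart. Of those 2 only CDL day 4 replicate 1 enters here, and without it alone 1960 were higher and 2310 lower. With each array centred on its median 2666 were higher and 2223 lower.

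Anterior presomitic and somite genes rose in 10 and fell in 1 of 15 (10 and 2 adjusted over the list alone, mean 1.88 ± 0.56, adjusted p = 4.59e-06, and adjusted p = 0.157 with an estimated correlation). Among them were Uncx at 5.72, Meox2 at 4.28, Meox1 at 4.22 and Dmrt2 at 3.53. All 6 sclerotome genes rose (mean 1.96 ± 0.40, adjusted p = 1.70e-05, and adjusted p = 0.134 with an estimated correlation), and dermomyotome genes rose in 5 and fell in 1 of 9 (adjusted p = 0.000644, and adjusted p = 0.105 with an estimated correlation). All 13 primitive streak genes fell (mean -2.39 ± 0.39, adjusted p = 7.55e-14, and adjusted p = 0.00463 with an estimated correlation), as did 11 of 13 posterior presomitic mesoderm genes (12 adjusted over the list alone, adjusted p = 1.08e-10, and adjusted p = 0.0152 with an estimated correlation) and 12 of 14 Wnt targets (adjusted p = 7.19e-07, and adjusted p = 0.157 with an estimated correlation). Targets of p53 fell in 9 of 11 (adjusted p = 6.90e-05, and adjusted p = 0.0371 with an estimated correlation). These included Perp at -2.27 and Phlda3 at -1.89. Epithelial genes fell in 9 of 12 (adjusted p = 7.35e-06, and adjusted p = 0.208 with an estimated correlation). Examples were Krt19 at -3.19, Krt8 at -3.19 and Cdh1 at -3.07. Pluripotency genes fell in 12 of 23 (adjusted p = 7.91e-05, and adjusted p = 0.433 with an estimated correlation). Among them were Pou5f1 at -3.91, Fgf4 at -3.80 and Klf5 at -3.79. Without CDL day 4 replicate 1, which held 19.7% of the ES signal, 11 fell and 3 rose. Notochord genes rose in all 3 tested members (adjusted p = 0.0310, and adjusted p = 0.229 with an estimated correlation). These included the morphogen Shh at 1.99 and Foxa2 at 0.50, and this list was not past the threshold without the 2 arrays that stood apart (adjusted p = 0.0607). Cholesterol synthesis genes rose in 9 of 16 (adjusted p = 0.00120, and adjusted p = 0.157 with an estimated correlation). Examples were Msmo1 at 1.39 and Nsdhl at 0.85. Imprinted genes (8 higher and 5 lower of 18, 10 and 5 adjusted over the list alone, adjusted p = 0.0318, and adjusted p = 0.433 with an estimated correlation) had a higher mean. Glycolysis (1 higher and 9 lower of 15, 1 and 10 adjusted over the list alone, adjusted p = 0.00177, and adjusted p = 0.369 with an estimated correlation), germline (0 higher and 4 lower of 5, adjusted p = 0.0114, and adjusted p = 0.293 with an estimated correlation) and anterior Hox genes (1 higher and 6 lower of 13, adjusted p = 0.0361, and adjusted p = 0.572 with an estimated correlation) had lower means. Without the 2 arrays 10 anterior Hox genes fell, and 3 of the somite genes. Other counts were the same adjusted over the list alone. Day, line, strain and reporter changed together in this comparison too.

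The media were compared again at day 6 within the Pax3-sorted CK35 cells. Higher in CDL were the stress-response gene Nupr1 (3.38 ± 0.23, adjusted p = 1.76e-07), Dll1 (2.14 ± 0.25), Aldh1a2, which makes retinoic acid (1.95 ± 0.16), Lmo2 (1.93 ± 0.18), Klf4 (1.92 ± 0.25) and Cth, an enzyme of cysteine synthesis (1.83 ± 0.20). Lower in CDL were Asb4 (-3.18 ± 0.15), the ETS factor Fli1 of endothelium and blood (-3.03 ± 0.13, and -2.40 as the mean of its probe sets), the homeobox gene Otx2 of the anterior neural plate and epiblast (-2.79 ± 0.24), Tgfbi (-2.57 ± 0.19), the ephrin receptor Epha3 (-2.36 ± 0.11), the proteoglycan Lum (-2.22 ± 0.14) and the imprinted Notch ligand Dlk1 (-2.06 ± 0.26). Pax3 was higher in CDL (0.76 ± 0.15, adjusted p = 0.00323), and Msgn1 differed by 0.46 ± 0.14 (adjusted p = 0.0679). Of all genes tested, 456 were higher and 488 lower, and 73 and 104 of these differed at least 2-fold.

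Notch and segmentation clock genes were higher in CDL in 7 of 14, the same adjusted over the list alone (mean 0.64 ± 0.17, adjusted p = 9.61e-06, and adjusted p = 0.173 with an estimated correlation). Among them were Hey1 at 1.26, Nrarp at 1.25 and Notch1 at 1.15. Wnt targets were higher in 4 and lower in 1 of 14 (7 and 1 adjusted over the list alone, adjusted p = 0.000362, and adjusted p = 0.293 with an estimated correlation). These included Tnfrsf19 at 1.74 and Nkd1 at 1.48 against the antagonist Dkk1 at -1.84. Mitotic genes were lower in 6 of 16 (10 adjusted over the list alone, mean -0.35 ± 0.06, adjusted p = 3.48e-07, and adjusted p = 0.0222 with an estimated correlation). Examples were Mki67 at -0.74, Cdc20 at -0.59 and Bub1b at -0.55. Embryonic fibroblast genes were lower in 5 of 10, the same over the list alone (adjusted p = 1.70e-05, and adjusted p = 0.0152 with an estimated correlation). Among them were Lum and the matrix gene Postn at -0.70. Imprinted genes were lower in 6 of 18 (10 adjusted over the list alone, adjusted p = 4.90e-05, and adjusted p = 0.173 with an estimated correlation). Without the 2 arrays that stood apart 11 were lower. Members that moved were Dlk1 and Peg10 at -0.97. Endoderm genes were lower in 3 of 7 (5 adjusted over the list alone, adjusted p = 0.000140, and adjusted p = 0.149 with an estimated correlation). Sox17 stood at -1.40, and 5 were lower without those arrays. Mesenchymal genes were lower in 3 of 10 (4 adjusted over the list alone, adjusted p = 0.00242, and adjusted p = 0.157 with an estimated correlation). An example was Snai2 at -1.79.

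Endothelium and blood genes were lower in 4 and higher in 1 of 10 (5 and 1 adjusted over the list alone, adjusted p = 0.0189, and adjusted p = 0.134 with an estimated correlation). These included Emcn at -1.23 and the VEGF receptor Kdr at -0.99 against Lmo2. Lateral plate genes were lower in 3 of 10 (5 adjusted over the list alone, adjusted p = 0.0188, and adjusted p = 0.134 with an estimated correlation). An example was Myl7 at -1.22. Anterior presomitic and somite genes were higher in 6 and lower in 3 of 15 (7 and 3 adjusted over the list alone, mean 0.38 ± 0.25, adjusted p = 0.0447, and adjusted p = 0.477 with an estimated correlation). Among them were Uncx at 1.59 and Aldh1a2 at 1.95 against Epha4 at -1.20. FGF and ERK targets (1 higher and 0 lower of 12, 4 and 0 adjusted over the list alone, adjusted p = 0.0280, and adjusted p = 0.534 with an estimated correlation) and immediate early genes (3 higher and 0 lower of 11, 4 and 0 adjusted over the list alone, adjusted p = 0.0166, and adjusted p = 0.320 with an estimated correlation) had higher means in CDL. RDL day 6 replicate 1, which correlated least with its mates, is in this comparison. Without the 2 arrays that stood apart these 5 lists were not past the threshold, with adjusted p of 0.0774 for endothelium, 0.172 for lateral plate, 0.239 for the somite genes, 0.729 for FGF targets and 0.0635 for immediate early genes. The count of 944 genes rose to 1512 without RDL day 6 replicate 1 and to 1776 without both arrays, where 889 of the 944 kept their direction and call. It was 442 when the 6 arrays were fitted alone, and there Pax3 was not past the threshold (adjusted p = 0.0664, with 0.000821 to 0.0664 over its alternatives). Another split of these 6 arrays, CDL replicates 1 and 3 with RDL replicate 1 against the rest, called 3102 genes. Without RDL day 6 replicate 1 the remaining RDL arrays all lie on 1 side of that split. The higher counts may thus hold that split as well as the medium, and do not show a firmer medium difference.

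**Figure D3:**
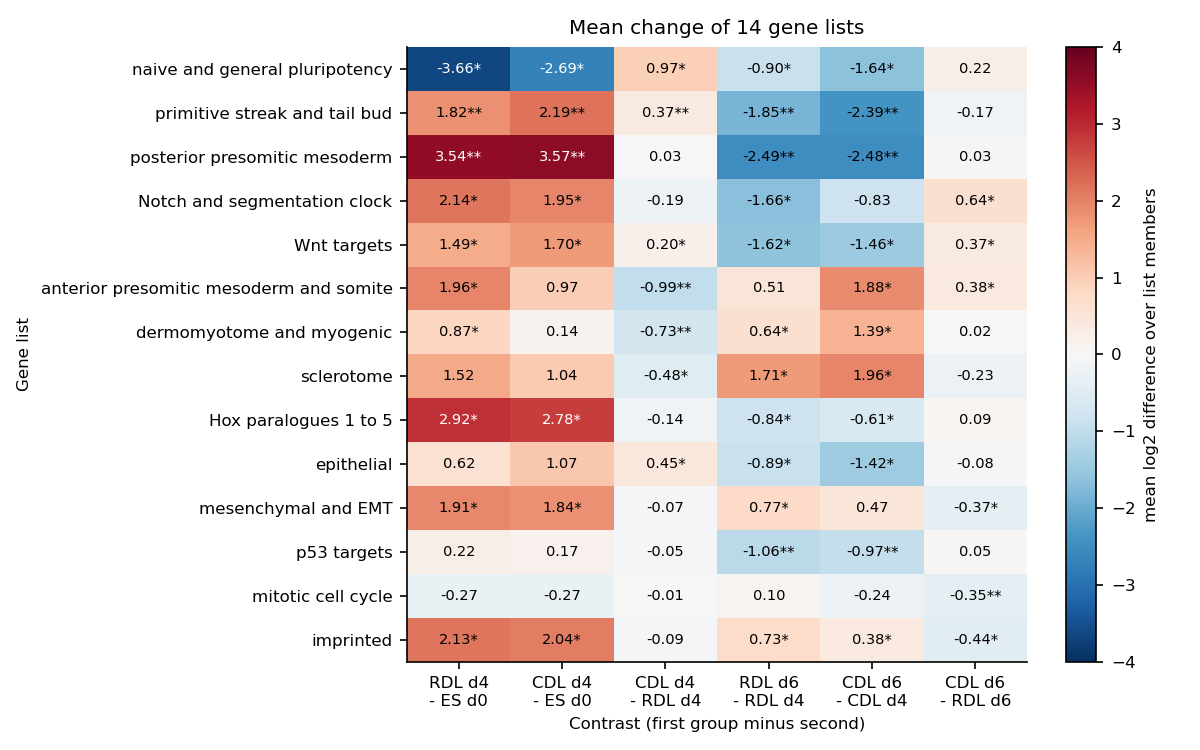
Mean log2 difference (color scale) over the tested members of 14 gene lists (vertical axis) in 6 comparisons (horizontal axis, group named first minus the other), with 1 asterisk for lists past adjusted p 0.05 and 2 for those also past it with an estimated correlation. The mean of the somite genes in CDL against RDL was -0.99 at day 4 and 0.38 at day 6, the latter with adjusted p = 0.477 with an estimated correlation and adjusted p = 0.239 without the 2 arrays that stood apart. Streak genes fell from day 4 to day 6 in both media (-1.85 and -2.39).

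Whether the medium difference itself differed between the day 4 and day 6 cells was tested as an interaction, positive where CDL gained on RDL. The somite genes Tcf15 (3.46 ± 0.31, adjusted p = 6.10e-06), Uncx (2.58 ± 0.47), Meox1 (2.58 ± 0.25) and Efnb2 (2.58 ± 0.37) and the stress gene Nupr1 (2.98 ± 0.33) had the largest positive values. Otx2 (-3.12 ± 0.34), the hormone gene Trh (-3.05 ± 0.28), the endothelial factor Fli1 (-3.003 ± 0.19, and -2.30 as the mean of its probe sets), Asb4 (-2.75 ± 0.21) and Tgfbi (-2.71 ± 0.27) had the largest negative ones. Tcf15 was lower in CDL at day 4 (-1.96) and higher at day 6, whereas Meox1 was lower at day 4 (-2.42) with 0.15 at day 6, which did not pass. The interaction of Pax3 was 1.61 ± 0.21 (adjusted p = 0.000158) and that of Msgn1 -0.32 ± 0.20 (adjusted p = 0.504). It passed for 286 genes upward and 382 downward.

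Of the 15 anterior presomitic and somite genes, 10 had a positive and 1 a negative interaction (10 and 2 adjusted over the list alone, mean 1.37 ± 0.39, adjusted p = 4.14e-10, and adjusted p = 0.0725 with an estimated correlation). Of the 9 members lower in CDL at day 4, 4 were higher at day 6 (Tcf15, Fgf18, Dmrt2 and Pax3, the gene of the day 6 sort), 1 was lower (Cer1) and 4 did not pass. Dermomyotome genes had 5 positive and 1 negative interactions among 9 (6 and 1 adjusted over the list alone, adjusted p = 0.000308, and adjusted p = 0.0885 with an estimated correlation). Notch genes had 6 positive ones among 14 (7 adjusted over the list alone, adjusted p = 1.71e-06, and adjusted p = 0.157 with an estimated correlation). These included Dll1 at 2.23 and Hey1 at 2.13. Primitive streak genes had 4 negative ones among 13 (9 adjusted over the list alone, mean -0.54 ± 0.10, adjusted p = 4.77e-07, and adjusted p = 0.0152 with an estimated correlation). Examples were Evx1 at -0.90 and Mixl1 at -0.85. Across all genes the medium differences of the 2 days correlated weakly (r = 0.10, rho = 0.11, genes not being independent replicates). There were 127 genes called on both days, 55 higher and 39 lower in CDL on both, against 13.2 and 7.40 for independent lists, and 33 in opposite directions. Of these 12 were higher at day 4 and lower at day 6, and 21 the reverse, against 14.1 and 6.91 for independent lists. Without both arrays that stood apart 9 streak genes had a negative interaction. The interaction count of 668 rose to 1216 without RDL day 6 replicate 1 and to 1237 without both arrays that stood apart. As for the media at day 6, these higher counts may hold the other split of the day 6 arrays as well as the medium. Because line and reporter changed with the day, the interaction cannot be assigned to any 1 of them.

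**Figure D4:**
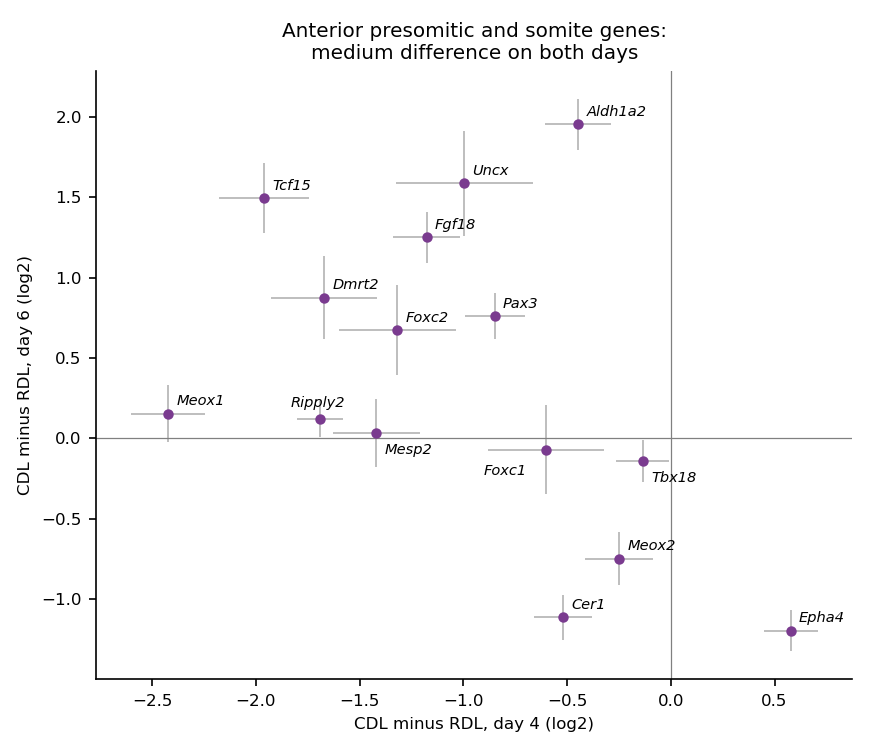
Medium difference, CDL minus RDL on the log2 scale, at day 4 (horizontal axis) and day 6 (vertical axis) for the 15 tested anterior presomitic mesoderm and somite genes, with SE of the fit as bars. Meox1 lay lowest at day 4 (-2.42) and Aldh1a2 highest at day 6 (1.95), while Epha4 lay on the other side of both (0.58 and -1.20).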

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

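The tests of undifferentiated cells, of a wrong label, of single arrays and of the cell lines were chosen after the results were seen, and the counts over other splits of the samples were planned.

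CDL day 4 replicate 1 lay nearer to the ES arrays than its mates did. A median ES share of 19.7% over 102 genes fits undifferentiated cells in that sample, and a mirror set of 109 genes gave 16.9% (interquartile range 9.54 to 22.6). RDL day 6 replicate 1 had a mirror value of 19.8% with an ES share of 0.167%, so the mirror value alone does not speak for ES cells. The array correlated better with its mates than with the ES arrays, by 0.082, which argues against an ES array under a wrong label, and on the log2 scale Sox2 stood at 10.12 on this array, against 11.75 in ES cells and 6.32 and 5.83 on its mates. A candidate explanation, as a hypothesis, is a sample with about this share of ES-like cells, which a clean sort for the Msgn1 reporter would remove, and no biological explanation was tested.

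The pluripotency list was higher in CDL than in RDL at day 4 (adjusted p = 1.30e-08, and adjusted p = 0.288 with an estimated correlation), and so was the epithelial list (adjusted p = 1.70e-05, and adjusted p = 0.211 with an estimated correlation). Without CDL day 4 replicate 1 the mean of all 23 pluripotency genes was 0.27 (SE 0.09), against 0.97 with it. Most of the mean thus went with that array, while a remainder above 0 by more than 2 SE argues against those cells as its whole cause. For the epithelial list the mean was 0.36 (SE 0.14) without the array and 0.45 with it, which argues against them as the whole cause there too. These SE, and those of the next paragraph, are over genes, which are not independent, and do not measure the spread between arrays. Both arguments thus hold best for the members past the threshold without the array, 4 of 23 and 4 of 12. The 4 pluripotency members past the threshold without the array were Pou5f1 (1.13), Dppa2 (1.12), Klf5 (1.12) and Fgf4 (0.58). Lin28a stood at 1.04 and did not pass (adjusted p = 0.107), while Nanog stood at 0.15, Sox2 at -0.01 and Esrrb at -0.05. The medium stays open for the remainder, as untested.

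Somite genes were lower in CDL at day 4 (mean -0.99) and higher at day 6 (0.38), the latter call being lost without the 2 arrays that stood apart (adjusted p = 0.239) and with an estimated correlation (adjusted p = 0.477). The interaction passed (adjusted p = 4.14e-10), and gave adjusted p = 0.0725 with an estimated correlation. The list's mean interaction of 1.37 was 1.31 (SE 0.39) without CDL day 4 replicate 1 and 1.20 (SE 0.37) without RDL day 6 replicate 1, with 11 of 15 members past the threshold each time, which argues against either array as the whole cause. It cannot speak against the structure of the day 6 samples described below, which spans both media. CDL day 6 replicate 2 stood apart in it too, and the list was not tested without that array. Line, strain and reporter changed with the day and stay open beside the medium, which was not tested apart from them.

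Hprt was dim on all 9 arrays of the E14 line (highest signal 46.8) and bright on all 6 of the CK35 line (lowest 851). Its log2 difference between day 4 and day 0 within E14 was -0.32, and a difference between the lines cannot be told apart from one between the days, because only CK35 was measured at day 6.

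The 6 arrays of a comparison split into 3 and 3 in 10 ways, the real one included, too few for a share under 0.05. In RDL day 4 against ES, CDL day 4 against ES, CDL against RDL at day 4, and day 6 against day 4 in RDL and in CDL, the real split was the 1 with the most genes (7079, 6967, 547, 3838 and 4881), and the highest other gave 0. Each other split mixes arrays of both groups, which widens the spread where the groups differ, so a count of 0 tells little. For the media at day 6, 2 splits gave at least 944, the real one included. The other called 3102 genes, parting CDL day 6 replicates 1 and 3 and RDL day 6 replicate 1 from the rest, which points to a structure of the day 6 samples. Residuals of 3 arrays correlate at about -0.50 within a group by construction. Those of RDL day 6 replicate 1 correlated at -0.89 and -0.88 with its mates and at 0.61 with CDL day 6 replicate 1. Those of CDL day 6 replicate 2 correlated at -0.77 and -0.72 with its mates and at 0.59 and 0.54 with RDL day 6 replicates 2 and 3, so this array stood apart as well. For the interaction 4 of 100 splits, the real one included, gave at least its 668 genes, a share under 0.05 that excludes chance only if arrays can be exchanged freely. The highest other gave 1436, and the structure of the day 6 samples speaks against free exchange, so the share is not taken here to exclude it.

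Genes among the largest differences between media on either day, or among the largest interactions, were picked out here because the interaction passed. Positive were Tcf15 (3.46), Nupr1 (2.98), Uncx (2.58), Meox1 (2.58), Efnb2 (2.58), Dmrt2 (2.55), Aldh1a2 (2.40), Dll1 (2.23), Lmo2 (1.98), Dleu7 (1.85), Zic5 (1.81), Ripply2 (1.81), Cth (1.79), Klf4 (1.68), Slc7a3 (1.67), Plat (1.60), Ptgds (1.502) and Nr2f2 (1.39). Negative were Defa31 (-1.46), Spx (-1.80), Dlk1 (-1.93), Mc2r (-2.08), Spink1 (-2.10), Mir99ahg (-2.18), Lum (-2.19), Epha3 (-2.41), Tgfbi (-2.71), Asb4 (-2.75), Fli1 (-3.003), Trh (-3.05) and Otx2 (-3.12). Defa31 belongs to a family of nearly identical defensin genes.

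Lists were picked out for the same reason. Means were positive for Notch (0.82), retinoic acid (0.48), anterior presomitic and somite (1.37), dermomyotome (0.75) and immediate early genes (0.31). They were negative for pluripotency (-0.74), streak (-0.54), endothelium (-0.16), endoderm (-0.55), epithelial (-0.53), fibroblast (-0.47), glycolysis (-0.29), mitosis (-0.34) and germline genes (-0.61). Without the 2 arrays that stood apart, 5 of these were not past the threshold: pluripotency (adjusted p = 0.720), retinoic acid (0.0906), endothelium (0.151), glycolysis (0.0733) and immediate early genes (0.0663). Without CDL day 4 replicate 1 alone the mean was -0.05 for pluripotency, -0.13 for glycolysis and -0.38 for germline genes. Of these 14 lists, 1 passed with an estimated correlation.

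Among 3659 probe sets without a single gene symbol, which the comparisons of genes did not use, 262 were at least 2-fold higher in RDL day 4 than in ES cells and 162 at least 2-fold lower.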

How the results depend on the processing

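All alternatives in this part were planned except leaving out CDL day 4 replicate 1 and RDL day 6 replicate 1 together, which was chosen after seeing the data. Results are numbers of genes past the threshold unless said otherwise, and where no reason is given the cause was not tested.

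A filter at the 75th percentile, which tests fewer genes, gave 361 for the media at day 4 (547 before) and 435 for the interaction (668 before). Testing all probe sets, of which a gene can have several, gave 13552 and 13037 for RDL and CDL day 4 against ES, 7138 and 8725 for day 6 against day 4, 1733 for the media at day 6 and 1034 for the interaction. Array weights gave 1700 for the media at day 4, 4153 at day 6 and 3681 for the interaction, with 50.8% of the day 4 genes higher in CDL against 65.6% before. Fitting only the 6 arrays compared gave 442 for the media at day 6 (944 before). A 2-fold minimum left 2435, 2205, 96, 758, 940, 177 and 252 in the order RDL day 4 and CDL day 4 against ES, media at day 4, RDL and CDL day 6 against day 4, media at day 6, and interaction. Leaving out the 2 arrays gave 1776 for the media at day 6 and 1237 for the interaction.

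Leaving out 1 replicate at a time, where the 2 arrays left in a group are assumed to vary like the other groups, gave 6428 to 6758 genes for RDL day 4 against ES, 6142 to 6814 for CDL day 4 against ES, 341 to 577 for the media at day 4 and 2921 to 3681 for day 6 against day 4 in RDL. For day 6 against day 4 in CDL it gave 3758 to 5446, for the media at day 6 684 to 1512, and for the interaction 482 to 1216. The lowest for the media at day 4 came without RDL day 4 replicate 2 (341) and then replicate 1 (353). The highest for the media at day 6 (1512) and the interaction (1216) came without RDL day 6 replicate 1. Both may hold the other split of the day 6 arrays, with which the media then go more closely.

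Median centring changed the share of genes higher at day 6 against day 4 from 44.2% to 54.5% in CDL and from 44.6% to 51.6% in RDL, with counts of 4889 and 3775. So the split into higher and lower genes in both comparisons rests on the scaling. Other constants, quantile normalization, no filter, the mean of probe sets and no intensity trend left all 7 counts within 1.5 times.

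With replicate number as a block, for which the pairing check met its rule only in RDL day 6 against day 4, the counts were 7293 and 7177 against ES, 634 for the media at day 4, 4210 and 5251 for day 6 against day 4, 1143 for the media at day 6 and 798 for the interaction. Same-number residual correlations elsewhere ran from -0.087 to 0.13 (RDL day 4 and ES), -0.11 to -0.018 (CDL day 4 and ES), 0.096 to 0.24 (media at day 4), 0.072 to 0.14 (CDL day 6 and day 4) and -0.24 to 0.61 (media at day 6). For the media at day 4 and for CDL day 6 and day 4, all 3 replicates also correlated best with their own number. A structure shared by replicate number is thus not excluded there.

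Of 224 list tests, 102 passed, and 17 with an estimated correlation. All 17 kept their direction. With fry 93 calls were kept, 9 lost and 50 gained, with the replicate block 101 kept, 1 lost and 4 gained, and without the 2 arrays 90 kept, 12 lost and 10 gained. Quantile normalization and a constant of 1 each lost 0 and gained 2. No call reversed under any of these 6 alternatives.

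For 144 results on named genes, 2803 alternative values gave the same call in 2788, lost it in 11, gained it in 4 and reversed it in 0. When only the groups compared were fitted, Chchd10 (0.0780), Dppa2 (0.108), Pla2g1b (0.141) and Epp13 (0.0522) for the media at day 4 and Pax3 (0.0664) at day 6 lost it by adjusted p. Leaving out 1 replicate moved the fold of 13 of these results by over 1.5 times, all of them with a CDL day 4 array left out. A constant of 1 moved 35, a constant of 30.3 moved 26, the mean of probe sets 24, leaving out the 2 arrays 13 and array weights 12, so sizes hold less well than calls. Dppa2 and Pla2g1b also lost it without any 1 of the RDL day 4 replicates, and over alternatives their adjusted p ran from 0.000325 to 0.108 and from 0.000338 to 0.141. It ran from 2.67e-05 to 0.0780 for Chchd10, from 5.52e-05 to 0.0522 for Epp13 and from 0.000821 to 0.0664 for Pax3. Msgn1 at day 6 (0.46, adjusted p = 0.0679) passed with a constant of 1, array weights, only the groups compared and the block, with 0.00875 to 0.202 over its alternatives. Signal over background limits the size of change of dim genes under every constant.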

Other observations

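The observations on guanylate-binding proteins and Tapbp, metallothioneins and line differences were chosen after their values were seen, and the list tests were planned.

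Gbp2 and Gbp2b, of the guanylate-binding proteins, were bright at day 4 in both media and dim at day 6. Gbp2 had a mean signal of 6.00 ± 0.240 (SD, n = 3) in ES cells, 426 ± 89.7 in RDL and 598 ± 59.9 in CDL at day 4, and 14.1 ± 6.55 and 11.4 ± 2.30 at day 6. Gbp2b rose by 3.99 ± 0.12 in RDL and 4.49 ± 0.12 in CDL from ES to day 4 and stood at -3.67 ± 0.12 and -4.18 ± 0.12 at day 6 against day 4. Tapbp, which loads peptides for antigen presentation, rose by 1.69 ± 0.15 in RDL and 2.46 ± 0.15 in CDL from ES to day 4. At day 6 against day 4 it stood at -2.95 ± 0.15 in RDL and -3.70 ± 0.15 in CDL. Line and day changed together at day 6, so the loss there has no single reading.

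The metallothioneins Mt1 and Mt2, which bind zinc, were higher in CDL than in RDL on both days. Mt1 differed by 2.07 ± 0.20 at day 4 and 1.44 ± 0.20 at day 6, and Mt2 by 1.80 ± 0.19 and 1.27 ± 0.19. The only other probe set of Mt1 was not called at day 4, and the mean of both gave 1.07. The interaction did not pass for either (adjusted p = 0.290 and 0.367). In ES cells, whose medium also held a GSK3 inhibitor, Mt1 had a mean signal of 1498 ± 79.6, against 262 ± 102 in RDL and 1087 ± 38.2 in CDL at day 4.

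There were 5 lists that passed with camera in none of the 7 comparisons. Fry called each of them in at least 1, with a lowest adjusted p of 0.00363 for BMP targets, 0.000490 for neural genes, 6.60e-05 for neural crest, 0.0119 for primed epiblast and 9.26e-05 for the sex chromosome list. Their lowest adjusted p with camera was 0.106 for BMP targets, 0.217 for neural genes, 0.134 for neural crest, 0.342 for primed epiblast and 0.109 for the sex chromosome list. Mean differences lay between -0.17 and 1.01 for BMP targets, between -0.84 and 0.31 for neural, between -0.25 and 0.68 for neural crest, between -0.36 and 0.34 for primed epiblast and between -0.76 and 0.26 for the sex chromosome list. Xist, of that last list, fell by 1.20 on the log2 scale in RDL day 4 against ES cells. The only tested member of Hox groups 10 to 13, Hoxc13, fell by 1.99 on the log2 scale in RDL and fell by 1.64 in CDL at day 4 against ES cells.

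There were 47 genes, Hprt among them, with a range under 1 on the log2 scale within the 9 E14 arrays and within the 6 CK35 arrays and a difference over 1.5 between the lines. Of these 27 were higher and 20 lower in CK35. Fap (4.44 in RDL day 6 against day 4) and Flrt2 (4.54), which were among the largest increases, belonged to them. With line and day confounded, the -0.32 found for Hprt within E14 shows only that its rise came after day 4 or with the other line, and both may hold.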
